A study of Mus musculus with 12 samples.

How the data were processed

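The series measured gene expression in mouse pro-B cells, early B-lineage cells sorted from bone marrow as B220+CD43+IgM-, on 12 one-colour arrays. The mice carried a tamoxifen-inducible Cre and either 1 or both alleles of Rptor flanked by loxP sites (fl/+ or fl/fl). Rptor encodes Raptor, the subunit that defines the mTORC1 kinase complex. Per the series' design text, cells came from mice 7 days after tamoxifen. Per the labels' protocols, they were cultured for 24 h with 25 ng/ml of IL-7, the cytokine that drives growth and survival of early B cells, or without it. Total RNA was amplified with NuGEN whole-transcript kits and labelled with biotin. The 4 groups held 3 arrays each. The labels do not say whether replicates of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

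The values are the log2 values the authors deposited for 41345 probe sets on each array. The submitters' processing notes name RMA, which corrects background, equalises array distributions and summarises probes on the log2 scale, and Partek 6.6, with neither role nor order. The genome build is not given in the sources used here, and no coordinates are printed. The deposited log2 values ran from 1.68 to 13.2, no value was missing, and array medians lay between 4.88 and 4.96. There are no detection calls or background measurements in the table, so a low log2 value cannot be told from absence of expression, and the number of arrays limits the precision. Array pairs correlated between 0.97 and 0.9903 across probe sets, and at most 2.01% of values in a pair were identical, so no array was treated as a repeat of another. Equalising distributions makes changes relative to the other genes on an array, so a shift of all transcripts together cannot be seen.

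Probe sets were named from the platform's annotation. It listed 25341 of the 41345 probe sets, of which 23521 had 1 symbol and 1820 had several; 16004 had no gene in that table. Of the named probe sets, 23328 matched the RefSeq gene table of assembly GRCm38.p6 by gene identifier, and 0 symbols needed updating. Only probe sets with 1 symbol were tested, which left out Rag1. For 1082 genes with several such probe sets the brightest over all arrays was taken, and none of them had probe sets called in opposite directions in any comparison. This left 22180 genes, with no filter on dim ones.

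A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 8 residual and 4.79 prior degrees of freedom). It tested 5 comparisons, which were the IL-7 response in each genotype, the difference between genotypes in each treatment, and the interaction of genotype and IL-7. All tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Errors beside log2 fold changes are standard errors from this fit, and a group value is a mean with its SD over 3 arrays. The Rptor probe set was also compared with an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

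Before the data were examined, 31 gene lists covering mTORC1, IL-7 and FoxO signalling, B-cell identity, growth, metabolism, cell division, stress, interferon response and the markers of other cell types that the sort could hold were fixed. Of their 697 entries 626 were measured. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists within a comparison. Beside it stand camera with an estimated correlation, and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. Camera called 20, 20, 14, 18 and 14 lists in the 5 comparisons in the order given above, and 10, 8, 1, 8 and 7 of these calls held with an estimated correlation.

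The rule for naming genes was also fixed in advance. Per comparison it takes, among called genes whose groups do not overlap in any array, the 10 largest rises and the 10 largest falls by log2 fold change, leaving out gene-model names, microRNAs, snoRNAs and immunoglobulin or T-cell receptor segments. For the interaction the overlap condition is dropped. It adds the 3 members with the smallest p of each called list, and in every comparison Rptor, Il7r, Cish, Socs2, Pim1, Myc, Ccnd2, Bcl2, Rag1, Rag2 and Igll1. Where under 5 genes pass, the 5 with the smallest p are named with values alone. Genes named outside this rule are said to have been chosen after their values were seen.

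The alternatives tried were median and cyclic loess scaling of the arrays, leaving out dim genes (mean log2 value up to 4.933, which kept 11634 genes), averaging a gene's probe sets, testing all probe sets one by one, limma with a trend or robust prior, an unmoderated linear model, array weights, the replicate number as a block, fitting the compared groups alone and leaving out each array in turn. A further alternative, chosen after seeing the data, left out 2 arrays together. The script was tested on simulated data with 200 of 22180 genes changed. For the IL-7 response in fl/+ it recovered 57% of changes of 0.5 and 99% of changes of 1 on the log2 scale, with 12 wrong calls. For the interaction it recovered 24% and 82%, with 6 wrong calls.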

Results

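Gene expression was measured on 12 arrays of sorted mouse pro-B cells, 3 for each combination of genotype (Rptor fl/+ or fl/fl, both after tamoxifen) and treatment (24 h with 25 ng/ml IL-7 or untreated). Along the axis of greatest variance, which held 45.7% of it, the 6 fl/+ arrays lay between -30.5 and -13.2 and the 6 fl/fl arrays between 3.17 and 36.6. The next axis held 20.8% of the variance, and on it every untreated array lay above 0 and every IL-7 array below 0. Among transcripts typical of other bone marrow cells, Siglech, a receptor of plasmacytoid dendritic cells, averaged 11.61 ± 0.07 in untreated fl/+ cells, S100a8, a neutrophil calcium-binding protein, 11.77 ± 0.07 and Prtn3, a neutrophil granule protease, 5.27 ± 0.03 on the log2 scale (SD, n = 3), all chosen after their values were seen.

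The Rptor probe set (17259177) did not differ between genotypes. Its log2 fold change in fl/fl against fl/+ was -0.03 ± 0.07 untreated (SE, limma adjusted p = 0.87; exact two-sided permutation p = 0.7) and -0.08 ± 0.07 with IL-7 (adjusted p = 0.57; exact permutation p = 0.3). With 3 arrays against 3 the exact test cannot go below 0.1. Where its probes lie relative to the deleted part is not known from the labels, so it checks nothing about the deletion.

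The question of what IL-7 changes in sorted pro-B cells with an intact Rptor allele was addressed in the fl/+ arrays. In either genotype, a changed share of cell types during culture was not separated from changed expression within pro-B cells. The largest rises were Pcp4, a calmodulin-binding peptide (log2 fold change 5.57 ± 0.22 (SE)), and Socs2, a STAT5-induced inhibitor of cytokine signalling (4.38 ± 0.17, from 3.64 ± 0.28 to 8.01 ± 0.21 (SD, n = 3)). Enpep (3.5), Myl10 (3.49), Clgn (3.19), Cish, another STAT5-induced inhibitor (2.76), the fatty acid desaturase gene Scd1 (2.76), Crhbp (2.75), the growth regulator Myc (2.40) and Mpzl2 (2.18) followed. Ccnd2, which encodes cyclin D2, rose by 1.89 ± 0.18, and the kinase gene Pim1 and the survival gene Bcl2 each by 0.94. The falls were smaller, led by Smim22 (-1.34), Olfr433 (-1.30), the cytokine gene Il15 (-1.09), Ifit3b (-1.01), Pkib, Cstdc4 and Phf11 (each -0.97), Ms4a6c and Ifnb1 (each -0.96) and Lgr5 (-0.95). Values for Il7r (-0.30, adjusted p = 0.093), Rag2 (-0.80, adjusted p = 0.17) and Igll1 (0.75, adjusted p = 0.37) did not pass the test.

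**Figure D1:**
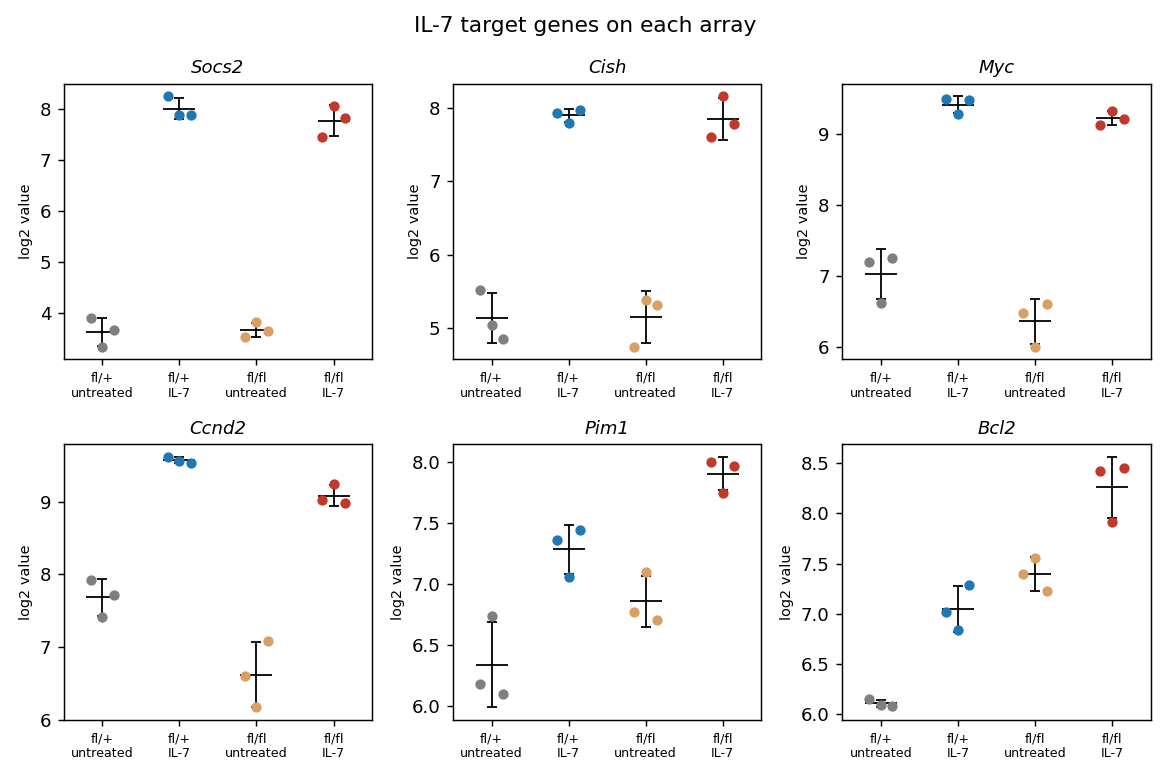
Log2 values of 6 IL-7 target genes on each of the 12 arrays by group, with bars for the mean and SD of 3 arrays. Socs2, Cish, Myc, Ccnd2, Pim1 and Bcl2 were higher with IL-7 in both genotypes, and Bcl2 was higher in fl/fl than in fl/+ in both treatments.

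Genes for making ribosomes, nucleotides and proteins rose together with IL-7 in fl/+ cells. Of 34 measured ribosome biogenesis genes 33 rose and 1 did not pass the test (median 0.83; 34 rose adjusted over the list alone), with Nop58 at 1.46 and Wdr75 at 1.14. Of 22 MYC targets 20 rose (21 adjusted over the list alone), among them the chaperonin gene Hspd1 (1.24), Pa2g4 (1.20) and Nop56 (1.00). All 18 aminoacyl-tRNA synthetase genes rose, both over all genes and adjusted over the list alone, including Eprs (0.96), Gars (1.02) and Kars (0.77). Of 20 nucleotide synthesis genes 17 rose (18 adjusted over the list alone), led in p by Ppat (1.70), Tyms (1.30) and Uck2 (1.77). DNA replication and G1/S genes rose in 27 of 30 cases (29 adjusted over the list alone), with Gins1 at 1.70, Mcm6 at 1.13 and Mcm5 at 1.5, and 19 of 30 G2/M and mitosis genes rose (29 adjusted over the list alone), with Aurkb at 1.04, Kif20a at 0.92 and Plk1 at 1.23. The G2/M call was lost in the stricter test, with adjusted p = 0.15 with an estimated correlation.

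Further lists were called with IL-7 in fl/+ cells. Cytosolic ribosomal protein genes rose in 15 of 33 cases (18 adjusted over the list alone), among them Rpl3 (0.70), glycolysis genes in 9 of 18 (10), with Tpi1 at 1.36 and Pgk1 at 0.87, fatty acid synthesis genes in 5 of 12 (6), with Fasn at 0.63, and amino acid metabolism genes in 13 of 27 (15), with Shmt2 at 1.64 and Mthfd1l at 1.26, the numbers in brackets being adjusted over the list alone. Of 21 IL-7 receptor and STAT5 genes 8 rose and 1 fell (9 and 2 adjusted over the list alone). Among FoxO targets 4 of 20 fell (7 adjusted over the list alone), including the repressor gene Bcl6 (-0.91) and S1pr1 (-0.53), and Bcl2l11 rose by 0.52, with adjusted p = 0.12 with an estimated correlation. Oxidative phosphorylation genes rose in 12 of 37 cases (17 adjusted over the list alone), including Uqcrc1 (0.55), with adjusted p = 0.078 with an estimated correlation. Pro-B identity genes rose in 7 of 24 cases (9 rose and 4 fell adjusted over the list alone), including the surrogate light chain gene Vpreb2 (1.49), Bst1 (0.97) and Tcf3 (0.50), with adjusted p = 0.56 with an estimated correlation; the call was also lost without fl/+ untreated replicate 3 (adjusted p = 0.058), fl/+ IL-7 replicate 1 (0.069) or fl/+ IL-7 replicate 3 (0.1). Of 20 myeloid markers 9 fell (12 adjusted over the list alone), including Itgam (-0.65) and Camp (-0.57), and of 11 plasmacytoid dendritic cell markers 5 fell (9), including Pacsin1 (-0.44) and Siglech (-0.27). These had adjusted p = 0.094 and adjusted p = 0.097 with an estimated correlation. Cholesterol synthesis genes fell in 4 of 19 cases, including Hmgcs1 (-0.45), with adjusted p = 0.25 with an estimated correlation, and lysosome genes in 5 of 30 with 1 rise, Rragd (1.38), with adjusted p = 0.11 with an estimated correlation. Interferon and mature B-cell lists were called with 0 members past the test, at medians of -0.81 and -0.24, with adjusted p = 0.51 and adjusted p = 0.25 with an estimated correlation. The mature B-cell median was -0.15 without fl/+ IL-7 replicate 1.

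In all, 2618 of 22180 genes changed with IL-7 in fl/+ cells, 1745 higher and 873 lower, and 228 of them by at least 2-fold. Higher genes made up 66.7% of the calls, against 81% under median scaling of the arrays.

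In fl/fl cells IL-7 raised STAT5 target and growth regulator genes. Socs2 rose by 4.11 ± 0.17 (SE), Enpep by 4.10, Pcp4 by 4.05, Myc by 2.86, Cish by 2.70, Ccnd2 by 2.47, Vpreb2 by 2.27 and Clgn by 2.03, and the GTPase gene Gbp7 (2.91) and the chemokine gene Ccl22 (2.68) were also among the 10 largest rises. Pim1 (1.04) and Bcl2 (0.86) rose. The largest falls were Thbs1 (-1.11), Sdc1, which encodes the plasma-cell proteoglycan CD138 (-0.89), Bcl6 (-0.88), Rbm24 (-0.86), Plk2 and Retnlg (each -0.80), Itgam (-0.62), Cyp2r1 and Tnfrsf17 (each -0.60) and Mctp1 (-0.59). Igll1 was 1.44 higher with adjusted p = 0.2.

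The growth lists rose here too. MYC targets rose in 12 of 22 cases (16 adjusted over the list alone; median 0.45), ribosome biogenesis genes in 15 of 34 (22; median 0.38), nucleotide synthesis genes in 6 of 20 (15; median 0.36) and replication genes in 10 of 30 (18; median 0.42), the numbers in brackets being adjusted over the list alone. Examples are Nop58 (0.81), Ppat (0.96), Mcm6 (0.81) and Pole (1.04). Fewer members passed with 1 array left out, down to 6 ribosome biogenesis genes without fl/fl untreated replicate 1, and 6 MYC targets and 3 nucleotide synthesis genes without fl/fl IL-7 replicate 2. Of the aminoacyl-tRNA synthetases 0 of 18 passed over all genes and 5 adjusted over the list alone, at a median of 0.14, with Eprs at 0.34 (adjusted p = 0.066) and adjusted p = 0.074 for the list with an estimated correlation. Of the G2/M list 0 of 30 passed, at a median of 0.48 with Top2a at 1.09 (adjusted p = 0.18), and adjusted p = 0.25 for the list with an estimated correlation. This median was 0.22 without fl/fl untreated replicate 2 and 0.29 without fl/fl IL-7 replicate 2. Myeloid markers had a median of -0.30, with 1 of 20 fallen and 15 adjusted over the list alone. Of the NK markers Il2rb (1.01), Ccl5 (0.72) and Nkg7 (0.73) rose, and of the T-cell markers Thy1 (1.01) and Cd3e (0.79), with adjusted p = 0.18 and adjusted p = 0.2 for these lists with an estimated correlation. The NK call was lost without fl/fl IL-7 replicate 3 (adjusted p = 0.062), and the T-cell call without any of 9 of the 12 arrays (adjusted p up to 0.21, without fl/fl untreated replicate 1). In fl/fl untreated replicate 2 the pro-B identity list stood at -0.76 relative to untreated fl/+ cells, against -0.22 and -0.02 in the other arrays of its group. Of that list 2 of 24 members rose, Vpreb2 and Pax5 (1.01) (7 rose and 1 fell adjusted over the list alone), with adjusted p = 0.42 with an estimated correlation. Without that array its median was 0.03 and the call was lost (adjusted p = 0.45), and without fl/fl IL-7 replicate 2 the median was 0.06.

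Of the IL-7 receptor and STAT5 list 7 of 21 rose in fl/fl cells (9 adjusted over the list alone), and of the amino acid metabolism list 3 of 27 (7), with adjusted p = 0.072 for the latter with an estimated correlation. FoxO targets had 1 fall, Bcl6 (5 adjusted over the list alone; adjusted p = 0.072 with an estimated correlation). Lysosome genes had a median of -0.16 and glycolysis genes of 0.13 (0.08 without fl/fl IL-7 replicate 3), with 0 members past the test. Cytosolic ribosomal protein genes had a median of 0.08 and 1 rise (adjusted p = 0.072 with an estimated correlation), and plasmacytoid dendritic cell markers a median of -0.17 with 0 past the test (adjusted p = 0.27 with an estimated correlation, and 0.14 without fl/fl untreated replicate 3, where the median was -0.10, as it was without fl/fl IL-7 replicate 3). The mature B-cell (-0.11), cholesterol synthesis (-0.10) and fatty acid synthesis (0.04) lists were called at adjusted p between 0.025 and 0.047, and these calls were lost with an estimated correlation (adjusted p = 0.27, adjusted p = 0.5 and adjusted p = 0.12). The mature B-cell call was also lost without fl/fl untreated replicate 2 (adjusted p = 0.37), fl/fl IL-7 replicate 1 (0.058) or replicate 2 (0.08), and the cholesterol and fatty acid calls without any of 8 of the 12 arrays (adjusted p up to 0.14 and 0.12). The mature B-cell median was -0.05 without fl/fl untreated replicate 2, and without fl/fl IL-7 replicate 3 the cholesterol median was -0.05 and the fatty acid median 0.09 (0.01 without fl/fl untreated replicate 3 or IL-7 replicate 1).

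Altogether 269 genes changed, 223 higher and 46 lower, 42 of them by at least 2-fold. The count was 133 in an unmoderated model, 116 with these groups fitted alone, 135 and 175 without fl/fl untreated replicates 1 and 2, and 140 and 122 without fl/fl IL-7 replicates 1 and 2.

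**Figure D2:**
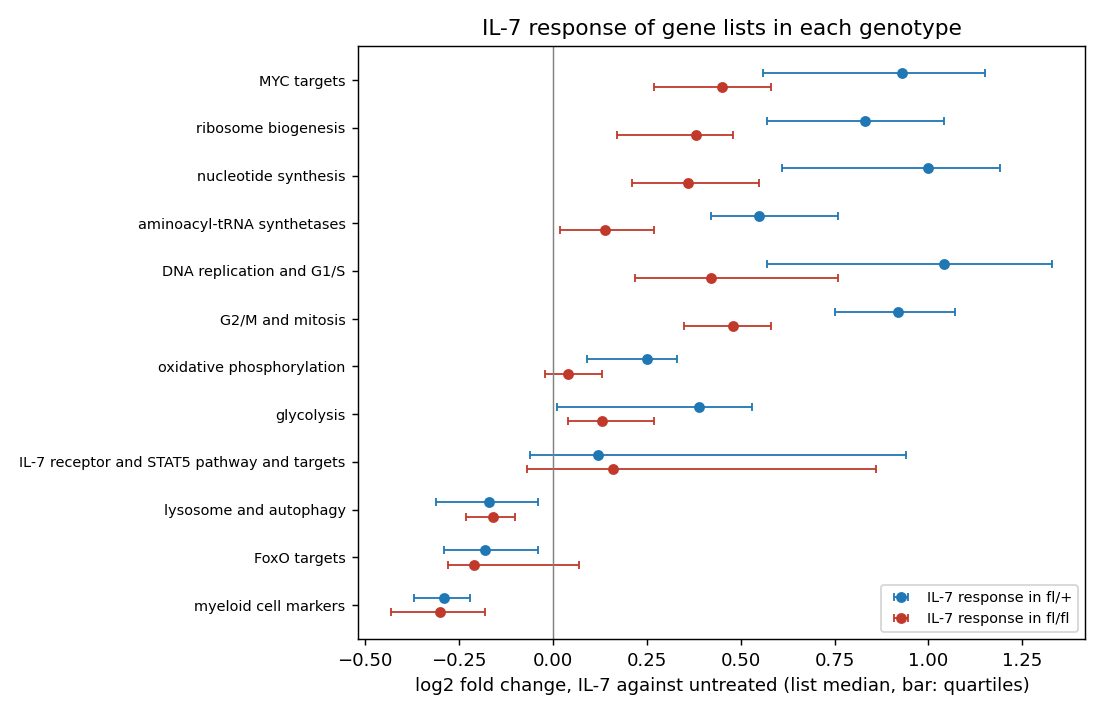
Median log2 fold change with IL-7 over the measured members of 12 gene lists, with bars for the quartiles, in fl/+ and in fl/fl cells. The ribosome biogenesis median was 0.83 in fl/+ and 0.38 in fl/fl, and the MYC target median 0.93 and 0.45.

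The responses of both genotypes were set against each other to ask whether loss of the second Rptor allele changes what IL-7 does. Across genes, which are not independent replicates, they correlated at r = 0.556 and share no array. Of the genes called 226 were called in both genotypes and 0 of these went opposite ways; 199 were higher in both, against 17.5 for independent lists, and 27 lower in both, against 1.81. Among genes called in fl/+ the fl/fl response had a slope of 0.448 on the fl/+ response, and among genes called in fl/fl the fl/+ response had a slope of 0.923 on the fl/fl response. Choosing genes by their call in 1 genotype favours a lower slope for the other, so neither slope alone measures the change in the response.

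The interaction, which tests the difference between the responses itself, was negative for growth genes. Of 34 ribosome biogenesis genes 10 had a smaller response in fl/fl (31 adjusted over the list alone; median -0.48), including Rrp1b (-0.84 ± 0.12, SE), Wdr12 (-0.77) and Wdr75 (-0.73). The same held for 7 of 20 nucleotide synthesis genes (15 adjusted over the list alone; median -0.59), including Tyms (-1.0), Ppat (-0.74) and Atic (-0.65), and for 6 of 22 MYC targets (14; median -0.47), including Srm, the spermidine synthase gene (-1.17), Mybbp1a (-0.74) and Pa2g4 (-0.64). It also held for 4 of 18 aminoacyl-tRNA synthetases (16; median -0.43), with Tars at -0.82, Gars at -0.78 and Eprs at -0.62, and for 5 of 30 replication genes (19; median -0.41), with Mcm5 at -0.98, Mcm2 at -0.95 and Cdc45 at -0.81. The amino acid metabolism list had 1 such member, Mthfd1l (-0.90), with adjusted p = 0.05 with an estimated correlation, and oxidative phosphorylation 1, Uqcrc1 (-0.59), with adjusted p = 0.17 with an estimated correlation. The cytosolic ribosomal protein (-0.20) and glycolysis (-0.12) lists were called with 0 members past the test. So were the G2/M (-0.45), interferon (1.10), plasmacytoid dendritic cell (0.19), cholesterol synthesis (0.13) and T-cell (0.15) lists, whose calls were lost with an estimated correlation (adjusted p = 0.52, adjusted p = 0.46, adjusted p = 0.35, adjusted p = 0.52 and adjusted p = 0.17). The G2/M median was -0.18 without fl/fl untreated replicate 3 (adjusted p = 0.044) and -0.69 without fl/fl untreated replicate 2, and the interferon median 0.61 without fl/fl IL-7 replicate 2. The glycolysis median was -0.20 without fl/+ IL-7 replicate 1 and -0.21 without fl/fl untreated replicate 1. The dendritic cell median was 0.11 without fl/fl untreated replicate 2 and 0.32 without fl/fl IL-7 replicate 3. The cholesterol median was 0.06 without fl/+ IL-7 replicate 2, 0.22 without fl/+ untreated replicate 2 and 0.26 without fl/+ IL-7 replicate 1. The dendritic cell call was also lost without fl/fl untreated replicate 2 (adjusted p = 0.099), the cholesterol call without fl/+ untreated replicate 1 (0.059) or fl/+ IL-7 replicate 2 (0.18), and the T-cell call without fl/+ untreated replicate 2 (0.12), fl/+ IL-7 replicate 3 (0.076), fl/fl untreated replicate 1 (0.09) or fl/fl IL-7 replicate 1 (0.06). Without fl/+ untreated replicate 2, 0 ribosome biogenesis genes, 0 MYC targets and 1 nucleotide synthesis gene passed.

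The largest negative interactions were Myl10 (-2.23 ± 0.30), Fabp5 (-1.90), Fam72a (-1.39), Nt5dc2 (-1.30), Cep76 and Lrr1 (each -1.22), Srm, Clgn (-1.16), Sac3d1 (-1.06) and the thioredoxin reductase gene Txnrd1 (-1.03). Of these, Myl10 and Fabp5 were already higher in untreated fl/fl than in untreated fl/+ cells. Positive interactions were fewer and were led by the chemokine gene Ccl6 (1.28), Ikzf2 (0.87), Gbp5 (0.83), Txk (0.81) and Ccl9 (0.79). The IL-7 targets had interactions of -0.06 ± 0.28 for Cish, -0.27 ± 0.24 for Socs2, 0.10 ± 0.23 for Pim1, 0.47 ± 0.24 for Myc, 0.57 ± 0.26 for Ccnd2 and -0.08 ± 0.21 for Bcl2, none past the test (adjusted p between 0.42 and 0.96). In all, 127 genes had a called interaction, 11 positive and 116 negative. The count was 59 and 13 without fl/+ untreated replicates 1 and 2, 25 and 7 without fl/+ IL-7 replicates 1 and 3, 27, 73 and 78 without fl/fl untreated replicates 1, 2 and 3, and 5 and 6 without fl/fl IL-7 replicates 1 and 3. It was 251 under median scaling, 218 without dim genes, 38 in an unmoderated model and 8 over all probe sets.

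Genotype was compared without IL-7 to ask what differs after 24 h of culture without the cytokine. The largest rises in fl/fl were Gpnmb, a lysosomal glycoprotein gene (4.69 ± 0.19, SE), the lipid chaperone genes Fabp4 (3.83) and Fabp5 (2.63), the cystine transporter gene Slc7a11 (3.11), Anpep (2.84), the proton pump gene Atp6v0d2 (2.79), Cd63 (2.69), the lectin genes Clec4n (2.36) and Clec4d (2.35), and Myl10 (2.34). Whether these rises lay within pro-B cells or in other cells of the sort was not tested. Bcl2 was 1.29 ± 0.15 and Il7r 0.76 ± 0.11 higher, and Ccnd2 was 1.06 ± 0.18 and Myc 0.66 ± 0.17 lower.

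The largest falls were mostly interferon-induced genes, namely Iigp1 (-3.97 ± 0.98), Ifi204 (-3.85), Ifi208 (-3.84), Oas1g (-3.56), Ifi214 (-3.42), Ifit1bl1 (-3.28), Isg15 (-3.27), Ifi205 (-2.95) and Ifit1 (-2.94), with Kdr (-2.98) the exception. Several of these belong to families of near-identical genes, whose probes can share signal. Of 19 interferon response genes 17 fell (18 adjusted over the list alone; median -2.40), with adjusted p = 0.26 with an estimated correlation. The fl/fl arrays differed among themselves on this list, at -2.49, -2.96 and -1.28 relative to untreated fl/+ cells, and 12 members fell without fl/fl untreated replicate 1.

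**Figure D3:**
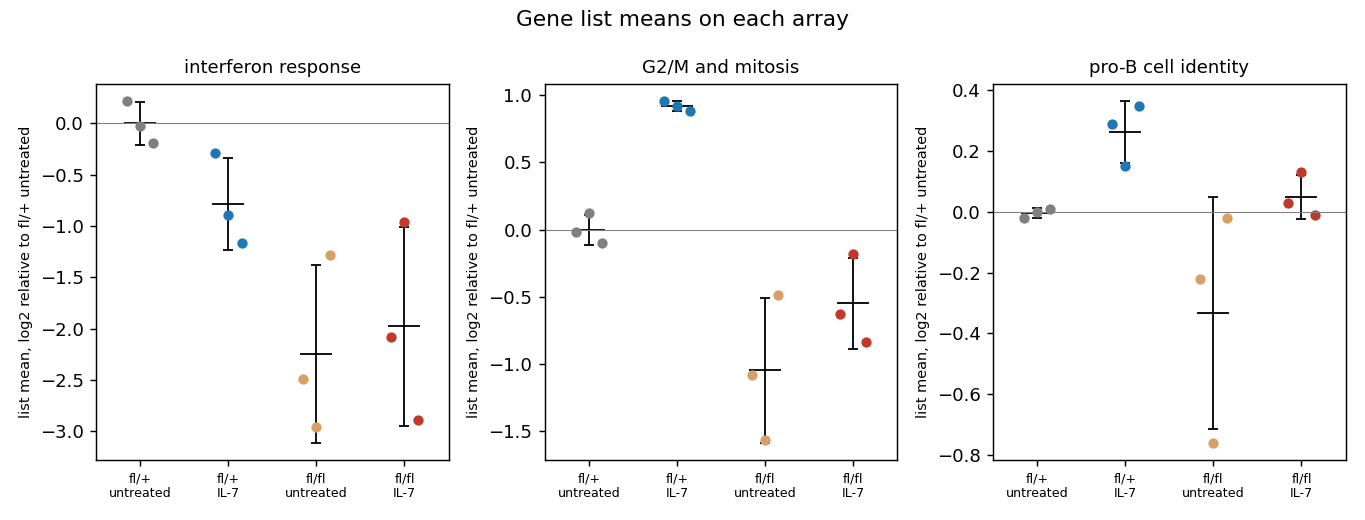
Mean log2 value of the interferon response, G2/M and pro-B identity lists on each array, relative to the mean of untreated fl/+ arrays, with bars for the mean and SD of 3 arrays. In fl/fl arrays the interferon mean ran from -2.96 to -0.96, and fl/fl untreated replicate 2 was lowest on all 3 lists.

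Dividing-cell genes were also lower. Of 30 G2/M genes 27 fell (30 adjusted over the list alone; median -1.01), including Nuf2 (-1.43), Kif4 (-0.95) and Aurkb (-0.76), and of 30 replication genes 18 fell (20; median -0.46), including Uhrf1 (-1.20) and Pole (-1.19). These lists had adjusted p = 0.26 and adjusted p = 0.23 with an estimated correlation, and fl/fl untreated replicate 2 was lowest on G2/M at -1.57 against -1.08 and -0.49. Cholesterol synthesis genes fell in 8 of 19 cases (10 adjusted over the list alone), including Fdps (-0.89) and Hmgcs1 (-0.76), with adjusted p = 0.26 with an estimated correlation. Lysosome and autophagy genes rose in 12 of 30 cases (16), including Gpnmb, Fnip2 (2.03) and the protease gene Ctsd (1.02), with adjusted p = 0.11 with an estimated correlation. FoxO targets rose in 10 of 20 cases and fell in 2 (13 and 3), including Pik3ip1 (1.12) and Cxcr4 (0.80), with adjusted p = 0.21 with an estimated correlation. Cytosolic ribosomal protein genes rose in 11 of 33 cases (18), including Rplp0 (0.74), a call kept with an estimated correlation (adjusted p = 0.048). Of 20 myeloid markers 8 rose and 4 fell (9 and 4), including Mpo, the neutrophil granule peroxidase (1.92 ± 0.12), Prtn3 (1.28) and Csf1r (1.14), with adjusted p = 0.37 with an estimated correlation. Of 11 plasmacytoid dendritic cell markers 5 fell and 1 rose (7 and 1), including Clec10a (-1.91) and Cd300c (-0.67), with adjusted p = 0.38 with an estimated correlation. Numbers in brackets after a count are adjusted over the list alone.

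Further lists were called in untreated fl/fl against fl/+ cells. Oxidative phosphorylation genes fell in 8 of 37 cases (11 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation), and unfolded protein response genes fell in 4 of 19 with 1 rise (7 and 1; adjusted p = 0.38 with an estimated correlation). Of the mTORC1 and PI3K components 6 of 23 rose, Pik3ip1 among them (8; adjusted p = 0.26 with an estimated correlation), of ribosome biogenesis genes 7 of 34 (8, with 1 fall; adjusted p = 0.46 with an estimated correlation), and of mature B-cell markers 2 of 13 with 1 fall (3 and 1; adjusted p = 0.38 with an estimated correlation). The ribosome biogenesis call was lost without fl/+ untreated replicate 2 (adjusted p = 0.18) or fl/fl untreated replicate 3 (0.054), and the mature B-cell call without fl/+ untreated replicate 1 (0.1) or fl/fl untreated replicate 2 (0.21). Pro-B identity genes went both ways, with 5 of 24 higher and 6 lower (6 and 10 adjusted over the list alone; median -0.34, camera adjusted p = 0.26). Their median was -0.11 without fl/fl untreated replicate 2 (adjusted p = 0.67) and -0.47 without replicate 3, where the list was called (adjusted p = 0.009). STAT5 genes also went both ways, with 4 of 21 higher and 4 lower (median -0.01, camera adjusted p = 0.8).

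Without IL-7, 2720 genes differed, 1547 higher and 1173 lower in fl/fl, 361 of them by at least 2-fold. Higher genes were 56.9% of the calls, against 49.5% under cyclic loess scaling, where 1284 were higher and 1310 lower. The count was 1763 without fl/fl untreated replicate 1 and 1792 without replicate 2.

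**Figure D4:**
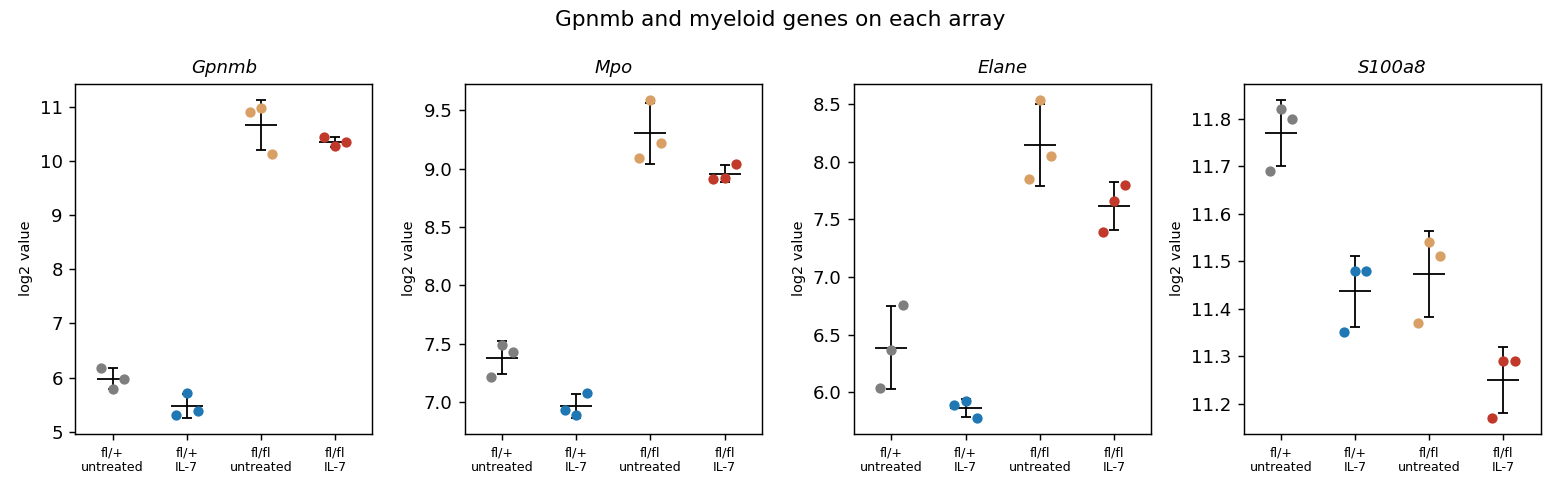
Log2 values of Gpnmb, Mpo, Elane and S100a8 on each of the 12 arrays by group, with bars for the mean and SD of 3 arrays. The fl/fl arrays lay above all fl/+ arrays for Gpnmb, Mpo and Elane, while untreated S100a8 averaged 11.77 in fl/+ and 11.47 in fl/fl.

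With IL-7 the rises in fl/fl again began with Gpnmb (4.88 ± 0.19, SE), Fabp4 (3.96), Slc7a11 (3.13), Ccl22 (3.10), Cd63 (2.62), Clec4n (2.43), Atp6v0d2 (2.41), Clec4d (2.34), Wfdc17 (2.15) and Fnip2 (2.12). For these rises too, the cell type they came from was not tested. The largest falls were Ifi208 (-2.64), Cd4 (-2.62), Slfn4 (-2.44), the secretin gene Sct (-2.23), Ly6g (-2.20), Rrm2, a ribonucleotide reductase subunit gene (-2.20), Car2 (-2.16), Pgam2 (-2.11), Lrr1 (-2.10) and Shcbp1 (-2.07). Bcl2 (1.21), Il7r (0.79) and Pim1 (0.62) were higher, and Myc (-0.20, adjusted p = 0.56) did not pass the test.

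All 30 G2/M genes fell (median -1.53), including Plk1 (-1.81) and Aurkb (-1.31), with adjusted p = 0.084 with an estimated correlation, and 28 of 30 replication genes fell (median -0.84), including Gins1 (-1.57), Mcm5 (-1.52) and Cdc45 (-1.39), with the same counts adjusted over the list alone. Ribosome biogenesis genes fell in 23 of 34 cases (27 adjusted over the list alone), including Nhp2 (-0.81), MYC targets in 15 of 22 (16), including Nme1 (-1.0), aminoacyl-tRNA synthetases in 15 of 18 (15), including Gars (-0.81), nucleotide synthesis genes in 16 of 20 (18), including Rrm1 (-1.38), oxidative phosphorylation genes in 21 of 37 (23), including Cox5a (-0.74), and glycolysis genes in 7 of 18 (9), including Pgk1 (-0.71). Amino acid metabolism genes fell in 11 of 27 cases, including Mthfd2 (-1.19), with Slc7a11 the rise, and adjusted p = 0.06 with an estimated correlation. Lysosome genes rose in 12 of 30 cases (14), FoxO targets in 8 of 20 with 1 fall (adjusted p = 0.056 with an estimated correlation), and myeloid markers in 9 of 20 with 2 falls, including Mpo (1.99) and Elane (1.75), with adjusted p = 0.2 with an estimated correlation. NK markers rose in 5 of 13 cases, including Klrk1 (1.01), with adjusted p = 0.22 with an estimated correlation. Numbers in brackets after a count are adjusted over the list alone. Interferon genes fell in 3 of 19 cases (8 adjusted over the list alone; median -1.29), namely Ifit1 (-1.65), Oas3 (-1.22) and Ddx58 (-0.91), with adjusted p = 0.43 with an estimated correlation, and 15 fell without fl/fl IL-7 replicate 2 but 0 without fl/+ untreated replicate 2.

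Cholesterol synthesis genes fell in 6 of 19 cases with IL-7 (7 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation) and fatty acid synthesis genes in 2 of 12 (4; adjusted p = 0.075 with an estimated correlation). Mature B-cell markers rose in 4 of 13 cases (5; adjusted p = 0.22 with an estimated correlation) and megakaryocyte markers in 2 of 7 (2; adjusted p = 0.37 with an estimated correlation). The cholesterol and megakaryocyte calls were lost without fl/+ IL-7 replicate 1 (adjusted p = 0.078 and adjusted p = 0.24), the megakaryocyte call also without fl/fl IL-7 replicate 2 (0.13), and the NK call without fl/+ IL-7 replicate 3 (0.067). Lists of pre-B differentiation, p53 targets, the BCL2 family, immediate early genes, erythroid markers and stromal markers were not called by camera in any of the 5 comparisons. Fry, which does not compare a list with other genes, called some of them in the lower direction, each on a few members. These were pre-B genes with IL-7 in fl/+ (3 of 18 fell and 1 rose, adjusted p = 0.0065) and fl/fl (1 and 1, 0.045) and in untreated fl/fl against fl/+ (5 and 2, 0.014), and p53 targets with IL-7 in fl/+ (4 of 20 fell and 1 rose, 0.021). In fl/fl against fl/+ they were erythroid markers untreated (2 of 8 fell, 0.013) and with IL-7 (1 of 8, 0.0073, at a median of 0.01), and stromal markers untreated and with IL-7 (2 of 14 fell and 1 rose in each, 0.03 and 0.02, at medians of -0.01 and -0.07).

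With IL-7, 2918 genes differed between genotypes, 1368 higher and 1550 lower in fl/fl, 316 of them by at least 2-fold. Higher genes were 46.9% of the calls, against 35.4% under median scaling, and the count was 1813 without fl/fl IL-7 replicate 3. The genotype differences in the presence and absence of IL-7 correlated at r = 0.718 across genes and share no array. Of the genes called, 1354 were called in both, 12 of them in opposite directions. The labels do not say whether cultures with and without IL-7 came from the same mice or sort. A cohort or sort difference between genotypes could then recur in both, so this is not a replication.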

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

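All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. Each gene and list in the next 2 paragraphs stands out because the IL-7 response differed between fl/+ and fl/fl cells by the test of the interaction. Values are log2 interactions, and negative ones mean a less positive or more negative response in fl/fl. This can come from a higher untreated level, which was 2.34 higher in fl/fl for Myl10 and 2.63 for Fabp5. With any array left out, the cytosolic ribosomal protein median in fl/fl against fl/+ was 0.17 to 0.22 untreated and 0.05 to 0.07 with IL-7.

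The interaction was called for 127 genes. List medians were -0.47 for MYC targets, -0.48 for ribosome biogenesis, -0.59 for nucleotide synthesis, -0.43 for aminoacyl-tRNA synthetases, -0.41 for DNA replication, -0.45 for G2/M, -0.20 for cytosolic ribosomal proteins, -0.18 for amino acid metabolism, -0.16 for oxidative phosphorylation and -0.12 for glycolysis. Of these, G2/M had adjusted p = 0.52, oxidative phosphorylation adjusted p = 0.17 and amino acid metabolism adjusted p = 0.05 with an estimated correlation, and the G2/M median ran from -0.69 to -0.18 with 1 array left out. Positive medians were 1.10 for interferon response, 0.19 for plasmacytoid dendritic cell markers, 0.15 for T-cell markers and 0.13 for cholesterol synthesis. All 4 calls were lost with an estimated correlation (adjusted p = 0.46, adjusted p = 0.35, adjusted p = 0.17 and adjusted p = 0.52), and the interferon median was 0.61 without fl/fl IL-7 replicate 2.

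Genes with a positive interaction were Ccl6 (1.28), Ikzf2 (0.87), Gbp5 (0.83), Txk (0.81), Ccl9 (0.79), Jak2 (0.69), Mxd1 (0.69), Pstpip2 (0.67) and Cyp2b19 (0.53). The largest negative values were those of Myl10 (-2.23), Fabp5 (-1.90), Fam72a (-1.39), Nt5dc2 (-1.30), Cep76 (-1.22), Lrr1 (-1.22), Srm (-1.17), Clgn (-1.16), Sac3d1 (-1.06) and Txnrd1 (-1.03). From the lists came Tyms (-1.0), Mcm5 (-0.98), Mcm2 (-0.95), Mthfd1l (-0.90), Rrp1b (-0.84), Tars (-0.82), Cdc45 (-0.81), Gars (-0.78), Wdr12 (-0.77), Ppat (-0.74), Mybbp1a (-0.74), Wdr75 (-0.73), Atic (-0.65), Pa2g4 (-0.64), Eprs (-0.62) and Uqcrc1 (-0.59).

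Growth genes responded less to IL-7 in fl/fl cells. Fewer IL-7-responsive cells in the fl/fl sort would shrink IL-7 responses, on the log2 scale large ones proportionally less than small ones. The response of Socs2, Cish, Pim1, Myc, Ccnd2 and Bcl2 in fl/fl was a median 1.04 times that in fl/+ (lowest 0.92). For the 33 ribosome biogenesis genes that rose in fl/+ it was 0.42 (upper quartile 0.52). Among these targets only Pim1 and Bcl2 had fl/+ responses close in size to the ribosome biogenesis median. The argument against fewer responsive cells therefore rests on those genes and is weak. Their interactions were 0.10 ± 0.23 for Pim1 and -0.08 ± 0.21 for Bcl2 (SE), wide errors beside a median of -0.48. Bcl2 also started 1.29 higher in untreated fl/fl cells. Fewer responsive cells are not excluded. The ribosome biogenesis median was -0.48 under cyclic loess, so it did not hang on further scaling of the deposited values. An effect of equalisation before deposit cannot be seen this way. A single aberrant array is argued against for this median, which was at most -0.45 with any array left out (largest camera adjusted p at the preset correlation = 2.6e-26). Calls of single genes were less stable. Called interactions went from 127 to 13 without fl/+ untreated replicate 2, where ribosome biogenesis genes lost their calls, and to 5 without fl/fl IL-7 replicate 1. A hypothesis is that growth genes depend more on the second Rptor allele than STAT5 targets do; a difference in cohort or sort between genotypes, which the labels do not separate, stays open and untested.

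Interferon genes were lower in untreated fl/fl cells, a call of the list lost with an estimated correlation (adjusted p = 0.26). A single aberrant array is argued against by the 12 to 18 of 19 members that fell with any array left out. The median was -2.46 under cyclic loess, against -2.40, so it did not hang on further scaling of the deposited values. An effect of equalisation before deposit cannot be seen this way. Fewer plasmacytoid dendritic cells, a source of interferon, stay open: of their 11 markers 5 fell and 1 rose, with adjusted p = 0.38 for the list with an estimated correlation and Siglech at 0.05 (adjusted p = 0.73). Genotype, and interferon exposure that differed by cohort or sort, stay open and were not tested.

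In regroupings of genotype within each treatment, 6 of 100, the real one included, gave as many interactions as the real 127, and the highest other gave 814, so chance cannot be excluded for this count by this test. All 5 others kept both genotypes of 1 treatment whole, which carries the genotype difference into the interaction. The 76 that kept none whole gave at most 1 gene, but they mix genotypes in every group. That puts the genotype difference into the spread, so few calls would come out whatever the interaction. For the other comparisons 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real counts were 2618, 269, 2720 and 2918 for IL-7 in fl/+, IL-7 in fl/fl, genotype untreated and genotype with IL-7, 1 split of 10 each, and the highest others were 0, 48, 0 and 0. These others mix the compared groups, which puts a real difference into the spread, so their low counts decide nothing.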

How the results depend on the processing

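Leaving out fl/fl untreated replicate 3 and IL-7 replicate 2 together was chosen after seeing the data; all other alternatives were planned. Of 6393 values of named genes under alternatives 0 reversed, 465 no longer passed the test and 56 newly passed. Losses were uneven, and 248 of the 465 were interaction values with 1 array left out, where 590 stayed the same. Of 3100 list values 0 reversed, 139 lost and 46 gained a call. The estimated correlation alone lost 10 calls for IL-7 in fl/+, 12 for IL-7 in fl/fl, 13 for genotype untreated, 10 for genotype with IL-7 and 7 for the interaction. The counts for IL-7 in fl/+ and for genotype in each treatment stayed within 1.5 times of 2618, 2720 and 2918 under every alternative that kept all arrays. The 269 genes for IL-7 in fl/fl became 133 in the unmoderated model, 116 with these groups alone and 143 without both arrays. The 127 interactions became 251 under median scaling, 218 without dim genes, 8 over all probe sets, 38 in the unmoderated model and 46 without both arrays. The correlation of IL-7 responses between genotypes, 0.556 across genes, became 0.649 without dim genes. With 1 array left out, counts ran from 1843 to 2648 for IL-7 in fl/+, from 122 to 303 for IL-7 in fl/fl, from 1763 to 2756 for genotype untreated, from 1813 to 2987 for genotype with IL-7 and from 5 to 101 for the interaction, and the correlation from 0.477 to 0.561. Fewer arrays leave fewer degrees of freedom; for the other changes the cause was not tested.

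Of 12 pairs of same-numbered arrays 4 deviated together (correlations over 0.1, range -0.53 to 0.28), so the numbers do not pair all arrays. Between treatments in fl/+ the same-number correlations were 0.28, 0.1 and 0.16, each highest or tied for its arrays. In fl/fl, untreated replicate 3 went with IL-7 replicate 2 (0.62) and untreated replicate 2 with IL-7 replicate 3 (0.44). Their same-number correlations were -0.53 and -0.48. Whether cultures of a genotype shared mice or sorts, under these or other numbers, stays open. With the replicate block the counts were 2422, 222, 2529, 2747 and 41 in the order IL-7 in fl/+, IL-7 in fl/fl, genotype untreated, genotype with IL-7 and interaction. The values hold no background measurement, so dim genes cannot be separated from absent ones.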

Other observations

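Tests in this part were chosen after the results were seen, except that of the immature myeloid list, whose rule was written before its genes' values were seen; gene groups and genes here were chosen after their values were seen.

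Small nucleolar RNA genes, which guide modification and processing of ribosomal RNA, rose with IL-7. Of 73 measured, 28 rose and 2 fell in fl/+ cells (median 0.39; camera adjusted p = 1.5e-13, and adjusted p = 0.0069 with an estimated correlation), and 10 rose in fl/fl (median 0.20; adjusted p = 0.0077 with an estimated correlation). Snora73b rose by 2.38 ± 0.15 (SE) in fl/+ and 1.19 ± 0.15 in fl/fl, and Snord99 by 2.03 ± 0.21 in fl/+, with 0.30 ± 0.21 in fl/fl (adjusted p = 0.66). The interaction of the group had a median of -0.16 with 4 of 73 genes called, all negative (camera adjusted p = 0.00061). That call was lost with an estimated correlation (adjusted p = 0.2). Probe sets of such genes inside introns can also read host transcripts.

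MHC class II genes, which present antigen, were higher in fl/fl cells, 3 of 7 untreated and 5 of 7 with IL-7, among them the transactivator gene Ciita (0.78 ± 0.15 and 0.83 ± 0.15) and H2-DMb2 (0.94 and 1.03). Of 11 C-type lectin genes of the Clec4 family 5 rose in each treatment, such as Clec4b2 (1.85 and 1.17) and Clec4e (0.89 and 1.32). Myeloid markers moved in the same comparisons, with 8 of 20 risen and 4 fallen untreated and 9 and 2 with IL-7 (adjusted p = 0.37 and adjusted p = 0.2 with an estimated correlation), and so did mature B-cell markers, with 2 of 13 risen and 1 fallen and 4 risen (adjusted p = 0.38 and adjusted p = 0.22 with an estimated correlation), a list that includes 4 of the 7 MHC class II genes. MHC class II and Clec4 genes lost their calls with an estimated correlation (adjusted p = 0.24 untreated and adjusted p = 0.21 with IL-7), and near-identical family members can share probe signal.

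The granule enzyme genes Mpo, Elane, Prtn3 and Ctsg were higher in untreated fl/fl cells (median 1.73, quartiles 1.60 to 1.79). More mature neutrophils are argued against by S100a8, S100a9, Ngp, Camp and Ltf, with a median of -0.30 and 4 of 5 fallen. A lower share of B cells with all other types raised in proportion would raise their markers, but 66 such markers had a median of -0.02 (quartiles -0.20 to 0.16). Markers of types absent from the sort could not rise, and replacement by 1 type would raise only its own. A lower share of B cells is therefore not excluded. More immature myeloid cells and altered expression within the sorted cells cannot be told apart: a separate list of 16 immature myeloid genes, 0 of them in a fixed list, had medians of 0.42 untreated and 0.38 with IL-7, with 8 risen and 1 fallen in each, between the bounds set. Sorting on B220 would remove most such cells, yet other myeloid transcripts were high in untreated fl/+ cells. S100a8 averaged 11.77 and Ngp 10.21 there, and Mpo 7.38, Ctsg 6.52, Elane 6.39 and Prtn3 5.27 on the log2 scale. In the immature list the largest untreated rises were Cst7 (1.20) and Ms4a3 (1.04), and the fall was Ly6c2 (-1.53).

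The fl/fl arrays differed among themselves, and a hypothesis is a graded extent of one genotype difference, which may reflect incomplete deletion. Each array's genotype difference was regressed on that of the other treatment, over genes called there. Slopes on genes that rose and on genes that fell were 0.92 and 0.69, 0.99 and 0.79, and 0.72 and 0.44 for untreated replicates 1, 2 and 3, and 0.78 and 0.77, 0.60 and 0.40, and 0.86 and 0.95 for IL-7 replicates 1, 2 and 3. The order of arrays was the same for genes that rose and fell in 2 of 2 treatments. With 3 arrays per treatment such orders can readily match by chance, and genes with large differences weigh most in these slopes. Deletion was not measured here, and a differing share of other cells or differing culture stays open.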
